A study of Mus musculus with 2 samples.

How the data were processed

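Spleen cells were profiled with droplet-based single-cell RNA sequencing. The labels name 2 mouse samples aged 6 to 8 weeks, 1 whose title marks it as the Wiskott-Aldrich syndrome model (WAS-KO) and 1 whose title marks it as wild type (WT). Per the labels' protocols, 3-prime libraries with unique molecular identifiers (UMIs) were sequenced on an Illumina HiSeq4000 or NovaSeq instrument, and the reference for mapping was mm10-3.0.0. The program used for mapping and counting, and its version, are not given in the sources used here. The deposited values are whole-number UMI counts per gene and cell barcode, with no normalization, and every value is a whole number.

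The deposited counts came as 1 table of 31017 gene symbols and 7524 barcodes. All 7524 barcodes carry the same suffix and stand in 1 alphabetical series, so nothing in the table ties a barcode to the WAS-KO or the WT sample. The table was therefore treated as 1 pooled sample, and no comparison between the genotypes was made. Whether it holds cells of both samples could not be established. No group was inferred from Was or any other transcript. Cells are not replicates, so no p-value and no standard error was computed, and differences between cell types have no replicate check. Sums of counts carry exact Poisson intervals, shares carry exact binomial (Clopper-Pearson) intervals, and ratios of counts carry exact conditional binomial intervals, all at 95%. These intervals cover counting error only. A count of 0 was taken to allow up to 3 counts.

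Barcodes with fewer than 200 detected genes or more than 10% of UMIs from mitochondrial genes were removed. Of the 7524 barcodes, 101 fell under the gene minimum, 857 exceeded the mitochondrial maximum and 936 failed either. Scrublet, run on the pooled 6588 remaining cells, called 137 doublets (2.08%), which were removed. The 6451 kept cells held 43297343 UMIs, with a median of 5290 UMIs and 1896 genes per cell and a 5th to 95th percentile range of 707 to 15508.5 UMIs. The smallest total of any deposited barcode was 500 UMIs.

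Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were reduced to 30 principal components, and cells were joined to their 15 nearest neighbours and clustered with the Leiden algorithm at resolution 1.0 and seed 0. Immunoglobulin and T cell receptor variable genes, haemoglobin genes, Xist, Y-linked genes and Was were kept out of the clustering. B cells, T and NK cells, and myeloid cells were then clustered again with the same settings. Clusters were named from 30 marker lists fixed before the data were examined, as "like" a cell type, where at least 3 markers were detected in at least 10% of the cluster's cells and the mean log2 level of the list lay at least 1.0 (classes) or 0.5 (subsets) above the mean over clusters. A cluster stayed unnamed where proliferation genes, pancreatic genes or markers of another type led it, or where its median depth was below the kept cells' median divided by 3 and none of its 10 leading genes was a marker of the name. These naming thresholds were set after the data had been examined. Clusters left unnamed are called by their leading gene.

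Summed UMIs of a class or subset were divided by its total and scaled to 1000000 (CPM). Ratios between subsets were ranked among genes with at least 100 UMIs over both. The rule for named genes was written for a comparison of WAS-KO with WT and was carried over to comparisons between cell types once the pooled layout was known. It takes the 12 highest and 12 lowest ratios of at least 1.5-fold for the B and T cell subset comparisons and 5 of each for the others, with immunoglobulin, T cell receptor, haemoglobin, sex-linked, mitochondrial and ribosomal protein genes and unnamed gene models left out, and from each fixed list the measured members with the largest ratios. The text gives a selection of these. In addition, 32 gene lists were fixed before the data were examined. Each list's median log2 ratio (1 CPM added) was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. For shares of cells with a UMI, cells were thinned to 1000 UMIs and shallower cells were left out. Gene coordinates came from GENCODE vM21 for GRCm38, the assembly that mm10 denotes, and all 664 named or listed genes had coordinates there.

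The ratio and list steps were tested on simulated counts drawn from the real totals of the marginal zone and follicular B cell-like cells, over 7314 genes with 200 changed. The interval left out 0 for 92.9% of the genes changed 2-fold, for 100.0% of those changed 4-fold and for 4.38% of the unchanged genes. The median error of the log2 ratio was -0.01 at 2-fold and -0.05 at 4-fold. Of unchanged lists, 5.0% fell outside the central 95% of random lists. Because the counts were drawn from subset totals and not from single cells, these rates describe counting error only. They leave out the spread between cells and are not error rates for the real comparisons. How often real unchanged genes or lists would pass these limits was not tested.

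Alternatives were other mitochondrial and gene limits, doublets kept, other clustering resolutions, clustering of thinned cells, other denominators, DESeq2 size factors and edgeR's TMM in place of total UMIs, other UMI minimums, and means in place of list medians. Clustering seeds 1 and 2, the CD8 share without the Ly6c2-led cluster, and list values without the cells of interferon-gene clusters, without 2 of the CD8 T-like clusters, without part of the monocyte-like class or without fixed markers of the compared subsets, were added after the data had been examined. Clustering each library alone could not be run, nor could weighting clusters by their WT shares. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and igraph 0.11.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.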

Results

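The series set out to catalogue the immune cells of the spleen in a mouse model of Wiskott-Aldrich syndrome, an inherited immune deficiency caused by loss of WASP, the actin regulator encoded by Was. The deposited table held 46882070 UMIs over 7524 barcodes, with a median of 4986.5 UMIs and 1828 genes per barcode and a largest total of 129686 UMIs. Of the 31017 gene symbols, 18393 had at least 1 UMI. The 2 samples of the labels, 1 WAS-KO and 1 WT, could not be separated in it. The values below therefore describe 1 pooled set of 6451 kept spleen cells and do not compare the genotypes.

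Was, the gene targeted in the model, was measured in most of the spleen's blood cell types. It lies on chromosome X at 8081453 to 8090498 (minus strand, GRCm38) and had 2767 UMIs in the kept cells, or 63.9 CPM (61.5 to 66.3). Its level was 98.0 CPM (83.4 to 114) in NK cell-like, 96.7 CPM (86.2 to 108) in monocyte-like, 83.8 CPM (72.2 to 96.9) in neutrophil-like, 78.7 CPM (74.4 to 83.2) in B cell-like and 67.8 CPM (62.1 to 73.8) in T cell-like cells. On 38 and 22 UMIs, it was 87.4 CPM (61.9 to 120) in macrophage-like and 35.4 CPM (22.2 to 53.6) in dendritic cell-like cells. The dendritic cell-like class leaves out most plasmacytoid dendritic-like cells, which fell mainly in the monocyte-like class and had 80.7 CPM (61.2 to 104). The Was level was 13.5 CPM (8.46 to 20.4) in plasma cell-like and 9.78 CPM (7.53 to 12.5) in erythroid-like cells, classes in which immunoglobulin and haemoglobin transcripts take up much of the total. The log2 ratio of erythroid-like to B cell-like cells was -3.01 (-3.39 to -2.65) by total UMIs and -1.30 with DESeq2 size factors. Within the lymphocytes, Was reached 101 CPM (89.0 to 115) in transitional B-like cells, against 77.2 CPM (71.4 to 83.5) in follicular B-like, 71.5 CPM (58.0 to 87.3) in marginal zone B-like, 72.6 CPM (64.7 to 81.2) in CD4 T-like and 56.5 CPM (48.4 to 65.6) in CD8 T-like cells. After thinning to 1000 UMIs, 8.0% of B cell-like, 7.3% of T cell-like and 1.5% of erythroid-like cells had a Was UMI, at median depths of 5063, 6897 and 11306 UMIs before thinning. In a library of 3-prime tags, a tag outside a deleted part of the gene can still be counted in a knockout, so these levels check no label. Whether the table holds both samples could not be established. Differences in Was between classes or subsets therefore cannot be told apart from differences in their share of WAS-KO cells. Among the sex-linked genes, Xist, which silences an X chromosome in females, had 3 UMIs, whereas the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had 3777, 3074, 1289 and 946.

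**Figure D1:**
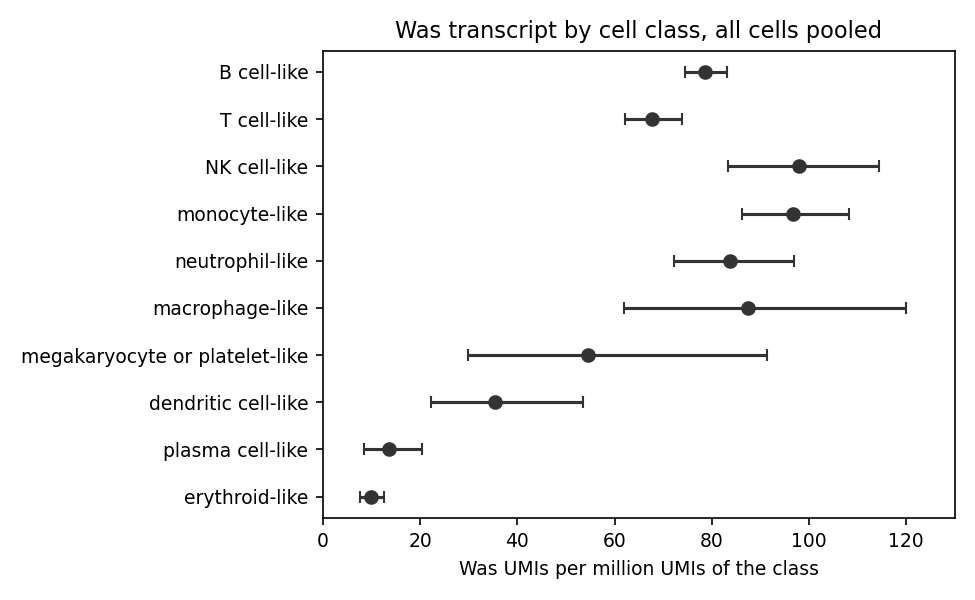
Was level in each cell class (x axis, CPM, UMIs scaled to a common class total) in the pooled spleen cells; points are the level and bars the exact 95% Poisson interval, which covers counting error only. The level was 98.0 CPM in NK cell-like and 9.78 CPM in erythroid-like cells.

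B cells made up the largest class of the spleen cells, followed by T cells, except under a stricter mitochondrial limit. B cell-like cells, defined by B cell receptor and surface genes such as Cd79a and Ms4a1, numbered 2767 of 6451 (42.9%, 41.7 to 44.1). T cell-like cells numbered 1069 (16.6%, 15.7 to 17.5), erythroid-like cells 567 (8.79%, 8.11 to 9.51), macrophage-like cells 342 (5.30%, 4.77 to 5.88) and NK cell-like cells 321 (4.98%, 4.46 to 5.54). Monocyte-like cells took 3.69%, dendritic cell-like cells 3.66%, neutrophil-like cells 3.01%, megakaryocyte or platelet-like cells 1.04% and plasma cell-like cells 0.977%. Unnamed clusters held 587 cells (9.10%). When the myeloid cells were clustered again, the 238 monocyte-like cells comprised 113 classical and 55 nonclassical monocyte-like cells, 47 plasmacytoid dendritic-like cells, 17 cells of an unnamed Mpo-led cluster with leading cell cycle genes, 5 cells of the Alas2-led cluster and 1 type 1 conventional dendritic-like cell. With at most 5% mitochondrial UMIs allowed, the B cell-like share was 7.50% and the T cell-like share 21.5%. Only 325 of the 2767 B cell-like cells (11.7%) lay within that limit, 11% of the 2957 kept cells within it, and 129 of these 325 fell into unnamed clusters when the cells were filtered and clustered again. The median mitochondrial share was 6.64% in B cell-like, 4.73% in T cell-like and 3.68% in NK cell-like cells. The macrophage-like share ranged from 3.15% with thinned cells to 10.9% with no mitochondrial maximum.

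**Figure D2:**
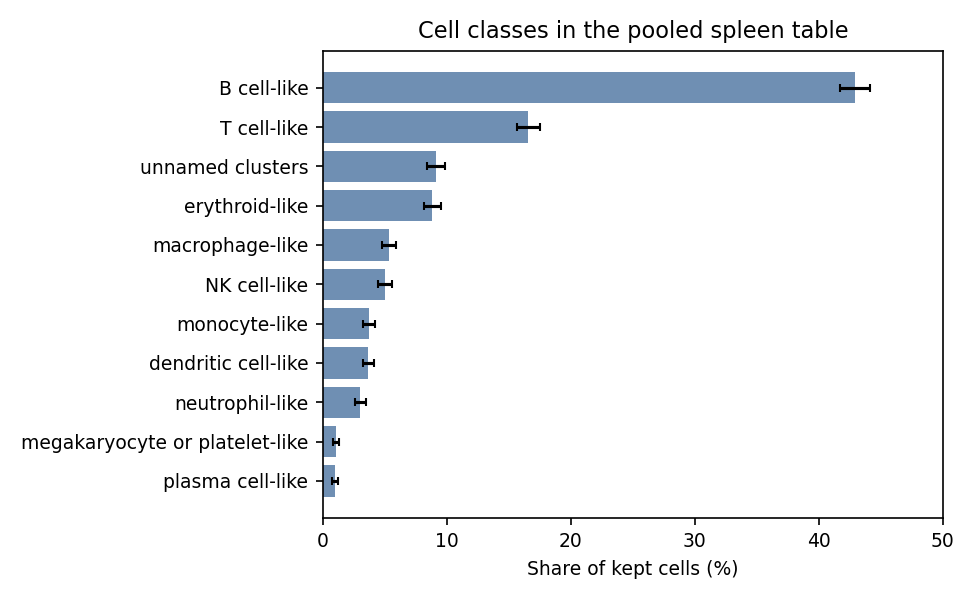
Share of the 6451 kept cells (x axis, percent) in each cell class; bars are the share and error bars the exact 95% binomial interval. B cell-like cells took 42.9% and T cell-like cells 16.6%.

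Among B cells, follicular cells outnumbered the transitional and marginal zone cells, here and under each alternative run. Follicular B-like cells numbered 1543 of 2767 (55.8%, 53.9 to 57.6), transitional B-like cells 512 (18.5%, 17.1 to 20) and marginal zone B-like cells 142 (5.13%, 4.34 to 6.02). Clusters led by Srm, Ighg2b and Gm26917 held the other 316, 127 and 127 cells. The marginal zone B-like share depended on the clustering and filter, with 8.58% without a mitochondrial maximum, 10.3% at resolution 2.0 and 10.6% at resolution 0.5. It was 18.1% at a mitochondrial maximum of 5%, where only 227 cells were B cell-like.

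**Figure D3:**
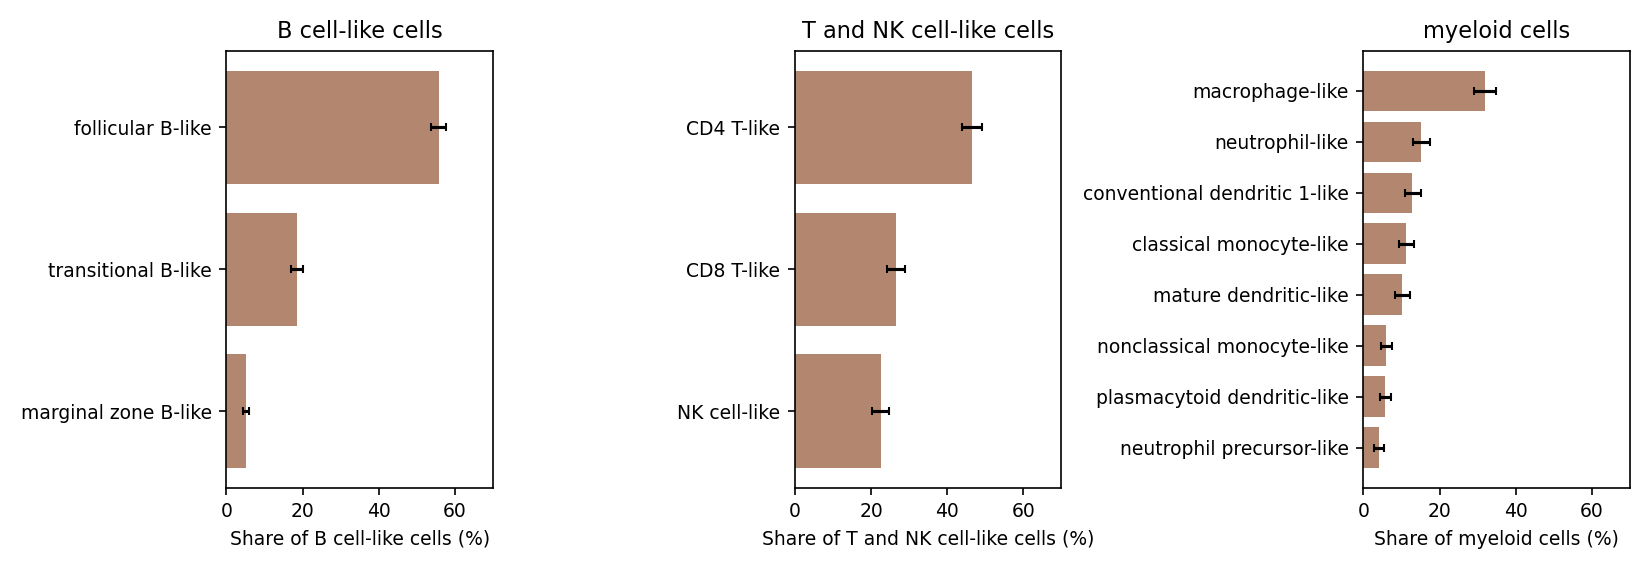
Share of each named subset (x axes, percent) among B cell-like cells, among T and NK cell-like cells and among myeloid cells; bars are shares and error bars exact 95% binomial intervals. Unnamed subclusters are part of each denominator and are not drawn.

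Marginal zone B cells sit at the edge of the white pulp and respond to blood-borne antigen, and follicular B cells recirculate through the follicles. The marginal zone B-like cells were set apart by S1pr3, a sphingosine-1-phosphate receptor, at 103 against 3.16 CPM (log2 ratio 5.02, 4.41 to 5.69), by Nebl, an actin-binding protein (5.37), by Cd9, a tetraspanin (3.59), by Fcrl5, an Fc receptor-like protein (3.45), and by Ahr, a ligand-activated transcription factor (3.12). Myof (4.39), Zc3h12c (4.22), Sema7a (3.82), Ffar2 (3.72), Rgs10 (3.67), AW011738 (3.46) and Ptpn14 (3.15) complete the 12 highest. Follicular B-like cells had more Fcer2a, the low-affinity IgE receptor CD23, at 451 against 46.5 CPM (-3.28, -3.66 to -2.92), and more Alcam (-3.27), Rflnb (-3.26), Ahnak (-3.51) and Wfdc17 (-3.49). The lowest ratios rest on 1 to 3 UMIs in the marginal zone B-like cells, as for Kctd14 (-5.47, -10.78 to -2.98), Rgl1 (-4.61, -9.92 to -2.11), Scimp (-4.17, -7.23 to -2.30) and Ifi44 (-4.17, -9.48 to -1.66). Apart from Zc3h12c, Sema7a, Ffar2, Fcrl5 and Ptpn14, the genes named here took part in the clustering, and S1pr3, Cd9, Fcrl5 and Fcer2a were among the fixed markers, so these genes describe what separates the clusters.

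Several fixed lists differed between the marginal zone and follicular B-like cells by more than matched random lists, though some of their genes took part in the clustering or were fixed markers. The 9 age-associated B cell genes had a median log2 ratio of 0.69 (percentile 99.5 of random lists), or 0.54 (97.95) without the marker Fcrl5, the 15 glycolysis genes 0.19 (99.2), the 92 oxidative phosphorylation genes 0.02 (99.9) and the 82 ribosomal protein genes 0.24 (100). The 10 genes of the naive T cell list, several of which B cells also express, had a median of -1.49 (percentile 0), with Bach2, a repressor of plasma cell differentiation, at -2.94 and the homing receptor gene Ccr7 at -1.99, or -1.12 (0.03) over the 8 genes that were not fixed markers. Immediate early and heat shock genes had a median of -0.36 (1.17), with Ier2 at -1.92 and Klf2 at -1.74. The type I interferon list had a median of -1.08 (percentile 0), with the antiviral genes Oas1a at -1.92 and Rsad2 at -1.89, but this rested on cells of Ifit3-led clusters. Without them, 131 and 1293 cells remained, and the median was -0.01 (64.8). The WASP and Arp2/3 list, 26 genes of the actin machinery, had a median of -0.20, within the range of random lists (-0.31 to 0.06), with Arpc5 at -0.73, Coro1a at -0.62 and Vasp at 0.67, and B cell receptor signalling genes had a median of -0.10 (55.7). The median gene had a ratio of -0.12. Haemoglobin and erythroid transcripts, listed beforehand as transcripts of other cells, stood at 8058 CPM in the marginal zone B-like and 2333 CPM in the follicular B-like cells. Without the 2 and 16 cells (the top 1%) with the most such UMIs, they stood at 1271 and 1477 CPM. Their source in these cells was not tested.

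The remaining B cell-like clusters are described by the genes and lists below, some of which led the clusters. Transitional B-like cells, the newest arrivals from bone marrow, had lower MHC class II genes than follicular B-like cells (median -0.66, percentile 0; H2-Aa -0.87) and lower ribosomal protein genes (-0.50, percentile 0), where the median gene stood at 0.14. The Ighg2b-led cluster had higher age-associated B cell genes (2.72, percentile 100), with Zbtb20 at 2.38 and Fcrl5 at 2.82, and higher trafficking and adhesion genes (0.54, percentile 100), with the integrin gene Itgb1 at 2.76 and the hyaluronan receptor gene Cd44 at 1.46. It was set apart by S100a6 (3.69) and Bhlhe41 (3.52), a transcription factor of innate-like B cells. Zbtb20, Itgb1, S100a6 and Bhlhe41 were among the 10 leading genes of that cluster, so these values describe it and test nothing. The Srm-led cluster had higher glycolysis (0.91), oxidative phosphorylation (0.54, percentile 100) and proliferation genes (0.68, percentile 99.9), with the lactate dehydrogenase gene Ldha at 1.75. At the level of all cells, an Ifit3-led cluster of 354 B cell-like cells (5.49%) was defined by interferon genes, on which the cells were clustered. Its medians over the other B cell-like cells, 2.81 for type I and 1.91 for interferon gamma genes, with Ifit1 at 5.61 and Cxcl10 at 5.27, therefore describe the cluster and test nothing.

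Plasma cells secrete antibody, and the 63 plasma cell-like cells carried a median of 27893 UMIs. Igha, the IgA heavy chain, took 52.4% of their 239864 heavy-chain constant UMIs, Ighm 22.0%, Ighg2c 19.2%, Ighg2b 4.13%, Ighg1 1.14% and Ighg3 1.13%. By the chain with the most UMIs in each cell, 27 were Igha, 20 Ighm, 11 Ighg2c, 3 Ighg2b, 1 Ighg1 and 1 Ighg3. The kappa chain Igkc took 95.9% of light-chain UMIs, against 69.5% in B cell-like cells. Among B cell-like cells, Ighd took 23.2% of heavy-chain UMIs in follicular and 4.97% in marginal zone B-like cells, where Ighm took 90.7%, and Ighg2b took 6.77% in the Ighg2b-led cluster against 0.400% in follicular B-like cells. Of the 127 cells of the Ighg2b-led cluster, 109 (85.8%, 78.5 to 91.4) had Ighm as the chain with the most UMIs and 10 (7.87%, 3.84 to 14.0) had Ighg2b. Relative to B cell-like cells, genes of secretion and the unfolded protein response had a median log2 ratio of 3.16, with Creld2 at 5.23 and Xbp1, the transcription factor of this response, at 5.0. MHC class II genes had a median of -4.04, with their activator Ciita at -7.51, and B cell receptor signalling genes -2.84. The WASP and Arp2/3 list stood at -1.99 (percentile 0.16), with the coactosin gene Cotl1 at -4.45 and Evl at -4.20. The median gene was at -1.31 in these cells, where heavy-chain and light-chain constant UMIs numbered 239864 and 560519 of 1629170. Whether they account for all of that shift was not tested, and the immunoglobulin genes themselves define the cluster.

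**Figure D4:**
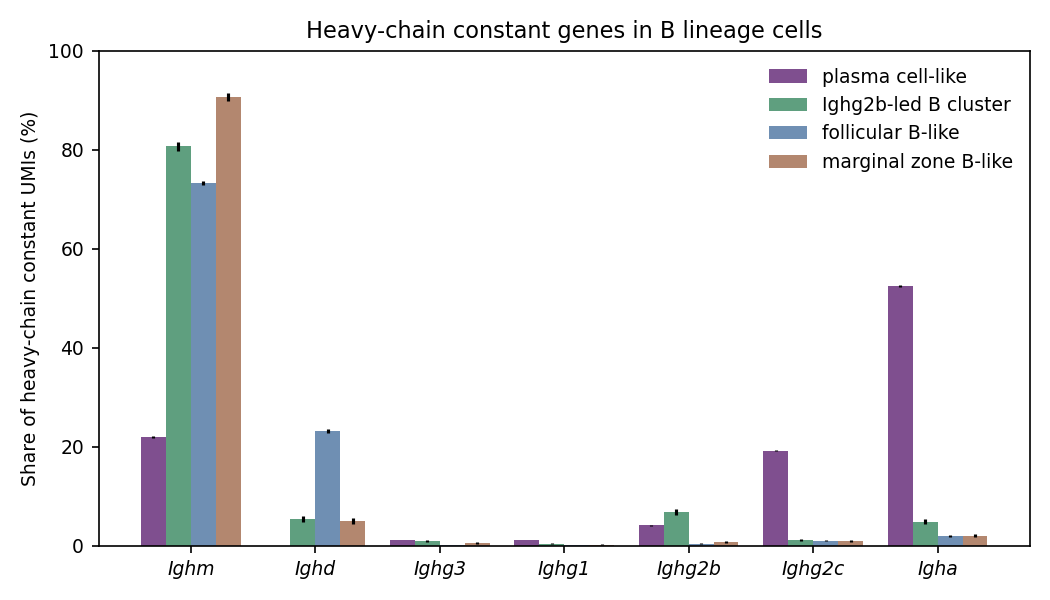
Share of heavy-chain constant UMIs (y axis, percent) by gene (x axis) in plasma cell-like cells, the Ighg2b-led B cluster, follicular B-like and marginal zone B-like cells; bars are shares and error bars exact 95% binomial intervals. Igha took 52.4% in plasma cell-like cells and Ighm 90.7% in marginal zone B-like cells.

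Among the 1390 T and NK cell-like cells, CD4 T-like cells outnumbered CD8 T-like cells. CD4 T-like cells numbered 646 (46.5%, 43.8 to 49.1), CD8 T-like cells 368 (26.5%, 24.2 to 28.9) and NK cell-like cells, clustered again within this group, 313 (22.5%, 20.3 to 24.8). Of the CD8 T-like cells, 113 formed a Ly6c2-led cluster whose leading genes included Trdc, a gamma delta T cell receptor gene, Cd160, Cxcr6 and Xcl1 but neither Cd8a nor Cd8b1. Its Cd8a level was 252 CPM, against 450 CPM in the Ccr9-led CD8 and 13.4 CPM in CD4 T-like cells, and its Trdc level was 207 CPM, against 23 CPM and 56.6 CPM; these genes were chosen after the clusters were seen. Without that cluster, CD8 T-like cells numbered 255 (18.3%, 16.3 to 20.5). Another 63 cells formed a cluster led by Il2ra, the interleukin-2 receptor alpha chain found on regulatory T cells, and stayed unnamed because B cell genes were among its leading genes. Foxp3, the regulatory T cell transcription factor, had a UMI in 46 T cell-like cells (4.30%), against 0.108% of B cell-like cells, with median depths of 6897 and 5063 UMIs. After thinning, the shares were 1.70% (1.01 to 2.68) and 0 of 2714 cells, which allows up to 0.111% of cells with a UMI at that depth.

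CD8 T-like cells were set apart from CD4 T-like cells by their co-receptor and, in some of their clusters, by cytotoxic genes. Cd8a and Cd8b1 had log2 ratios of 4.91 and 4.71, and Cd4, Cd40lg, the CD40 ligand of helper cells, and Zbtb7b, a transcription factor of the CD4 lineage, had -3.96, -3.33 and -2.63. The chemokine genes Xcl1 (6.70, 4.82 to 9.76) and Ccl3 (6.34, 4.46 to 9.40) had 2 UMIs each in CD4 T-like cells, as did the receptor gene Klra7 (6.34, 4.46 to 9.40). Ccl4 (4.55), the granzyme genes Gzmm (5.31) and Gzma (4.58) and the lectin-like receptor genes Klre1 (5.91), Klrc1 (5.10) and Klrd1 (4.53) were also among the 12 highest. The 70 cells of the Gzmk-led cluster held 1117 of the 1230 Gzma, 385 of the 469 Ccl4 and 124 of the 196 Klrc1 UMIs of the CD8 T-like cells. In the Ccr9-led cluster of 185 cells, Gzma, Ccl4 and Klrc1 had 9.57, 1.28 and 1.28 CPM, against 16.9, 6.58 and 1.88 CPM in CD4 T-like cells. Lower in CD8 T-like cells were Nav2 (-4.90, -7.19 to -3.32), Ly6c1 (-4.57), St8sia6 (-4.01), Pdlim4 (-3.92), Tbc1d4 (-2.90), Izumo1r (-2.81) and Maf (-2.30), a transcription factor of helper T cells. Apart from Zbtb7b, the genes named here took part in the clustering, and Cd8a, Cd8b1, Cd4 and Cd40lg were among the fixed markers of these subsets. These genes therefore describe what separates the clusters.

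Several list medians differed as well, though some list genes took part in the clustering or were fixed markers. Cytotoxic effector genes had a median of 3.16 (percentile 100) in CD8 over CD4 T-like cells, which rested on the Gzmk-led and Ly6c2-led clusters. The median was 1.87 (percentile 100) without the Gzmk-led cluster, 3.34 (percentile 100) without the Ly6c2-led cluster and -0.76 (percentile 0) without both, the opposite direction. Over all CD8 T-like cells, trafficking and adhesion genes had a median of 0.17 (99.8), with the chemokine receptor gene Cxcr3 at 1.35. T cell activation and inhibitory receptor genes had a median of -0.57 (percentile 0), with Icos at -1.30 and Maf at -2.30 but Cd160 at 4.02, naive T cell genes -0.43 (percentile 0), with Igfbp4 at -2.05, and T cell receptor signalling genes -0.19 (0.48), with Cd5 at -1.07 and Cd28 at -0.98. Cd5 was a fixed CD4 T marker. Cxcr3, Icos, Maf, Cd160 and Igfbp4 were among the leading genes of clusters pooled into these subsets. The medians of their lists therefore partly describe how the subsets were formed. Immediate early and heat shock genes stood at -0.35 (0.01), with Fos at -0.99. Type I interferon genes had a median of -0.74 (percentile 0), with Isg20 at -1.65 and Isg15 at -1.07. Without the cells of Ifit3-led clusters, 367 and 573 cells remained and the median was 0.21 (99.9), the opposite direction. Iron and haem recycling genes had a median of 0.58 (99.9), but -0.21 over members with at least 100 UMIs. The WASP and Arp2/3 list had a median of -0.02 (53.0), or -0.21 (0.95) without the Gzmk-led and Ly6c2-led clusters. Apart from this list and the cytotoxic effector list, no list was computed again without these clusters. Haemoglobin and erythroid transcripts stood at 1500 CPM in CD8 and 5715 CPM in CD4 T-like cells, and at 1300 and 1266 CPM without the 4 and 7 cells (the top 1%) with the most such UMIs.

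The clusters within the CD4 and CD8 T-like cells were led by genes of some of these lists, such as Maf, Icos, Igfbp4 and Ccl5, so the list medians between these clusters describe them and test nothing. The Maf-led cluster of 128 cells exceeded the Igfbp4-led cluster of 347 cells in T cell activation and inhibitory receptor genes (median 2.5), with the memory marker Cd44 at 4.58, the inhibitory receptor gene Ctla4 at 4.44 and the costimulatory receptor gene Icos at 3.12. Among the highest ratios of single genes was that of Ikzf2, at 8.22, on 327 against 3 UMIs. Before thinning, Foxp3 had a UMI in 13 of the 646 CD4 T-like cells. Whether regulatory T cells were part of the Maf-led cluster was not tested. Its naive T cell genes had a median of -2.10, and its WASP and Arp2/3 genes 0.63 (percentile 99.99), where the median gene stood at 0.28. The Ifit3-led cluster of 72 cells was defined by interferon genes, on which it was clustered, and its type I interferon median over the Igfbp4-led cluster (3.05) describes it. Among CD8 T-like cells, the Gzmk-led cluster of 70 cells exceeded the Ccr9-led cluster of 185 cells in cytotoxic effector genes (5.91), with Ccl4 at 9.16, Gzmb at 8.78 and Ccl5 at 7.48, and in WASP and Arp2/3 genes (0.80, percentile 100), with the actin genes Actg1 at 1.36 and Actb at 1.02, where the median gene stood at 0.23. NK cell-like over T cell-like cells, cytotoxic effector genes had a median of 3.30, with the perforin gene Prf1 at 4.43. Prf1, Gzma, Nkg7 and Klrd1 of that list were fixed NK cell markers, so its median describes the class and tests nothing. In the same comparison, type I interferon genes stood at -1.63 (percentile 0), with Ifi27l2a at -3.50, or -0.92 (percentile 0) without the cells of Ifit3-led clusters. The WASP and Arp2/3 median of NK cell-like over T cell-like cells was 0.44 (97.8), with Hcls1 at 0.86 and Arpc1b at 0.80, and the median gene stood at 0.19.

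Myeloid cells numbered 1010 and included macrophages, dendritic cells, monocytes and neutrophils. Macrophage-like cells numbered 322 (31.9%, 29.0 to 34.9), neutrophil-like cells outside the precursor-like cluster 154 (15.2%) and type 1 conventional dendritic-like cells 130 (12.9%). Classical monocyte-like cells numbered 113 (11.2%), mature dendritic-like cells 102 (10.1%) and nonclassical monocyte-like cells 60 (5.94%). Plasmacytoid dendritic-like cells numbered 57 (5.64%) and neutrophil precursor-like cells 40 (3.96%). The macrophage-like share of myeloid cells was 16.3% with at least 500 genes required and 49.4% without a mitochondrial maximum, and 252 of the 342 cells of the class (73.7%) had under 1000 UMIs.

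Macrophage-like cells over all other cells were set apart by genes for clearing old red cells and dead cells. Iron and haem recycling genes had a median log2 ratio of 5.38, with Spic, the transcription factor of red pulp macrophages, at 6.33, the haptoglobin-haemoglobin receptor gene Cd163 at 6.32, haem oxygenase Hmox1 at 6.18 and the iron exporter gene Slc40a1 at 5.99. Efferocytosis and complement genes had a median of 4.44, with the receptor tyrosine kinase genes Mertk at 7.17 and Axl at 6.32. Hmox1, Slc40a1, Spic and the complement genes C1qa, C1qb (6.41) and C1qc were fixed macrophage markers. Axl was among the leading genes of the macrophage-like cluster. The medians of both lists were therefore partly fixed by how the class was formed and named. Mature over type 1 conventional dendritic-like cells, NF-kB targets had a median of 2.20, with Ccr7, which guides dendritic cells to T cell zones, at 6.03 and Relb at 4.25, and MHC class II genes -1.39, with H2-DMb1 at -4.04 and H2-Ab1 at -2.19. Classical over nonclassical monocyte-like cells, neutrophil granule genes had a median of 1.59, proliferation genes 1.37, type I interferon genes 0.89 and efferocytosis and complement genes -1.41. F13a1, coagulation factor XIII, stood at 6.96 and the Fc receptor gene Fcgr4 at -4.28. Between the neutrophil clusters, the Ifitm1-led 65 cells exceeded the Ly6g-led 89 cells in inflammatory genes (2.73), with Il1b, the interleukin-1 beta gene, at 8.78 and the chemokine gene Cxcl2 at 4.90, whereas granule genes had a median of -1.85, with the antimicrobial genes Camp at -10.08, Ngp at -9.83 and Ltf at -9.12. The median gene stood at 0.52 there. Ccr7 and F13a1 were fixed markers and leading genes of the mature dendritic-like and classical monocyte-like clusters. Il1b led the Ifitm1-led and Ltf the Ly6g-led cluster among other genes, and Camp, Ngp and Ltf were fixed neutrophil precursor markers. The values between these myeloid clusters therefore describe them and test nothing.

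The share of cells with transcripts of dividing cells differed between groups. Mki67, a marker of cycling cells, had a UMI in 4.0% (3.51 to 4.54) of 5846 cells thinned to 1000 UMIs, with 605 shallower cells left out, and in 9.19% without thinning. The thinned share was 55.0% (46.7 to 63.2) in the unnamed Pclaf-led cluster of 180 cells, where Mki67 and other cell cycle genes are among those that define the cluster, 36.8% (21.8 to 54.0) in neutrophil precursor-like cells, 13.5% (10.7 to 16.7) in erythroid-like cells, 8.33% (4.84 to 13.2) in neutrophil-like cells as a whole, 8.33% (2.76 to 18.4, 5 of 60) in plasma cell-like cells, 6.33% (3.58 to 10.2, 15 of 237) in monocyte-like cells, 1.23% (0.656 to 2.09) in T cell-like cells and 0.516% (0.282 to 0.864) in B cell-like cells. Of the 342 macrophage-like cells, 252 were too shallow; the share was 6.67% (2.49 to 13.9) in the other 90 and 2.34% (1.01 to 4.56) over all 342 at 500 UMIs. Of the 15 monocyte-like cells with a Mki67 UMI, 11 were among the 17 cells of the Mpo-led cluster. Another gene of dividing cells, Top2a, had a UMI in 1.67% (1 of 60) of plasma cell-like, 1.22% of B cell-like and 7.17% of monocyte-like cells, so the plasma cell-like share of Mki67 was not matched by it. Over all other cells, the erythroid-like cells had a proliferation list median of 1.11 (percentile 100), with the ubiquitin-conjugating enzyme gene Ube2c at 2.65 and Mki67 at 1.75, where the median gene stood at -1.55.

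The genes of the WASP and Arp2/3 actin machinery, the pathway in which the targeted gene acts, were compared between each class and all other cells. Their median log2 ratio was 0.66 (percentile 97.6) in monocyte-like cells, with the Arp2/3 subunit gene Arpc1b at 1.32. Without the plasmacytoid dendritic-like and Mpo-led cells of that class, 174 cells remained and the median was 0.72 (96.9), inside the range of matched random lists (-0.07 to 0.76). It was 0.41 (99.7) in neutrophil-like cells, with Vasp, which extends actin filaments, at 1.38 and its relative Evl at -4.16. It was 0.60 (94.7) in NK cell-like, 0.43 (95.1) in dendritic cell-like, 0.38 (91.2) in macrophage-like, 0.18 (12.4) in B cell-like and 0.18 (24.0) in T cell-like cells, all inside the range of matched random lists. With DESeq2 size factors the medians were 1.33 in neutrophil-like, 0.26 in NK cell-like and -0.07 in B cell-like cells. In erythroid-like cells the median was -2.85 (0.01), with the coronin gene Coro1a at -4.23, and -1.29 with size factors. The list took 8.00% of UMIs in dendritic cell-like, 4.43% in macrophage-like, 4.36% in NK cell-like, 3.05% in T cell-like, 2.57% in B cell-like and 0.398% in erythroid-like cells.

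**Figure D5:**
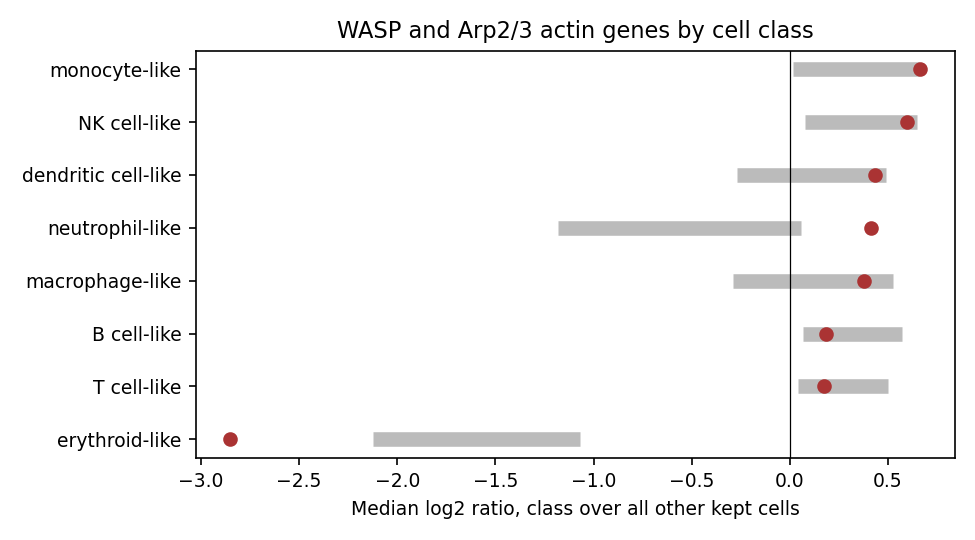
Median log2 ratio (x axis) of the 26 WASP and Arp2/3 actin genes in each class over all other kept cells (points), with the central 95% of 10000 matched random lists as grey bars. The points for monocyte-like and neutrophil-like cells stood at 0.66 and 0.41, and that for erythroid-like cells at -2.85.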

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

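The 14 enzyme genes, the test of free RNA as the only source, and the omission of the unnamed clusters were chosen after the data were seen. The criterion of the acinar cell test was written before its result was seen. Transcripts of the exocrine pancreas appeared in the kept spleen cells, above what a count of 0 would allow. The 14 digestive enzyme genes searched had 2915 UMIs, led by Ctrb1 (512), Cela1 (381), Pnlip (327), Try4 (293) and Prss2 (249), in 525 cells (8.14%, 7.48 to 8.83). The values argue against free RNA spread over all droplets as the only source, since the same UMIs spread equally over the cells would reach 36.4% of them, and 32.5% if spread by depth. The 1% of cells with the most enzyme UMIs, 65 cells, held 79.2% of them, and 71.1% when the single cell with 831 UMIs was left out. Several of these genes lead the Ctrb1-led cluster of 47 cells, so a concentration in few cells was partly fixed by their choice. Acinar cells, or doublets that hold one, stay possible as a source, but this share cannot decide it. The Ctrb1-led cluster of 47 cells held 66.9% of the enzyme UMIs, but its median cell had 9 and its cells also carried B cell markers, so a whole acinar cell in most of them is not shown. Free RNA stays open as a part of the signal. The classes could not settle it. With the unnamed clusters, the class with the most enzyme UMIs per cell exceeded the median class 11.7-fold, but these include the Ctrb1-led cluster, which the enzyme genes themselves define. Without them, the ratio was 2.17 over 8 classes (0.466 against 0.214), under the 5-fold that would count against free RNA, while the 90th percentile of the classes exceeded the 10th 8.17-fold, over the 3-fold that free RNA allows. No biological explanation was tested.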

How the results depend on the processing

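Clustering seeds 1 and 2 and the omission of Ifit3-led, Gzmk-led, Ly6c2-led, plasmacytoid dendritic-like and Mpo-led cells and of fixed markers from the lists were chosen after the results were seen; all other alternatives were planned. No paired analysis was possible because the table does not tie cells to samples. Among alternatives, class shares left their counting interval in 47 of 108 cases, B subset shares in 16 of 24, T and NK subset shares in 19 of 41, myeloid shares in 20 of 64, single ratios in 30 of 280 and list medians moved in 20 and reversed in 3 of 247. With at most 5% mitochondrial UMIs, class shares were 7.50% B, 21.5% T and 7.50% macrophage-like. Subset shares were 39.2% follicular and 18.1% marginal zone among 227 B cell-like cells, 35.5% CD4, 19.3% CD8 and 26.5% macrophage-like among myeloid cells. B cell-like cells lay mostly above that limit, and 129 of the 325 within it fell into unnamed clusters. Without a mitochondrial maximum the shares were 39.6% B, 14.9% T, 10.9% macrophage-like, 8.58% marginal zone, 43.8% CD4 and 49.4% myeloid macrophage-like. With at least 500 genes they were 47.3% B, 18.5% T, 4.61% macrophage-like, 70.4% follicular and 16.3% myeloid macrophage-like. With doublets kept they were 40.3% B, 6.57% macrophage-like, 53.0% follicular, 39.8% CD4, 29.1% CD8 and 26.6% myeloid macrophage-like. Resolution 0.5 gave 6.53% macrophage-like, 50.9% follicular, 10.6% marginal zone and 32.2% CD4, and resolution 2.0 gave 41.2% B, 46.9% follicular, 10.3% marginal zone, 43.8% CD4 and 21.6% CD8. Clustering of cells thinned to 1000 UMIs gave 46.1% B, 18.3% T and 3.15% macrophage-like. With erythroid-like and platelet-like cells out of the denominator, which raises every share, they were 47.6%, 18.4% and 5.88%. Seed 1 gave 41.5% B and 53.0% follicular, and seed 2 gave 41.6% and 59.8%. The Was log2 ratio of erythroid-like to B cell-like cells was -1.30 with DESeq2 size factors, -1.50 with TMM and -1.66 with totals lacking ribosomal, mitochondrial, haemoglobin and immunoglobulin genes. The share of cells with a Mki67 UMI was 9.19% without thinning and 2.62% at 500 UMIs, as depth sets it. Reversed were the iron and haem recycling list in CD8 over CD4 T-like cells, at -0.21 over members with at least 100 UMIs, the type I interferon list there, at 0.21 without Ifit3-led clusters, and the cytotoxic effector list there, at -0.76 without the Gzmk-led and Ly6c2-led clusters, which held most Gzma, Ccl4 and Klrc1 UMIs of the CD8 T-like cells. With the Ly6c2-led cluster unnamed, the CD8 share was 18.3%. Of the 24 named genes, minimums of 50, 300 and 1 UMIs kept 10, 2 and 7 for marginal zone over follicular and 15, 11 and 12 for CD8 over CD4. The WASP and Arp2/3 medians of both comparisons stayed within the spread of random lists under the alternatives run, except at -0.21 for CD8 over CD4 without the Gzmk-led and Ly6c2-led clusters; without the Gzmk-led cluster alone it was -0.14 (13.4). Except where a reason is given, the cause was not tested. Clustering each library alone and weighting clusters by WT shares could not be run. Depth limits what can be said of macrophage-like cells, at a median of 757.5 UMIs.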

Other observations

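The tests of Was counts and of haemoglobin UMIs in this part were set before their results were seen. The haemoglobin shares of median cells and the doublet score had no criterion set beforehand. Several groups of cells belonged to no named class or, among the B cell-like cells, to no named subset. The Pclaf-led cluster of 180 cells had a median of 4877.5 UMIs, and Pclaf encodes a factor that binds the replication clamp. The Pla2g2d-led cluster of 154 cells and the Ppp1r14a-led cluster of 109 cells were shallow, with 92 and 42 cells under 1000 UMIs and medians of 907 and 1186. The Gm26917-led B subcluster of 127 cells had a median of 1321 UMIs and a median mitochondrial share of 0.625%, against 6.64% in all B cell-like cells. The Fcna-led cluster of 97 cells held B cell markers at 5342 CPM and macrophage markers at 1858 CPM, where B cell-like cells had 7026 CPM of the former and macrophage-like cells 18454 CPM of the latter. The 936 barcodes that failed a filter had a median of 1243 UMIs and 16.0% mitochondrial UMIs, and haemoglobin genes took 10.6% of all UMIs in the table.

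Was counts were examined for a split among the B cell-like cells, as a mixture of cells with and without the transcript would give. The overdispersion of Was over 2767 B cell-like cells was 0.028 (bootstrap 95% interval -0.074 to 0.131), and 15.5% of 200 genes matched on their count had lower values, with a matched median of 0.214. In counts simulated from these cells, the overdispersion was 0.006 with every cell carrying the transcript, 0.241 with 20% of cells lacking it and 1.0 with 50%. The values argue against 20% or more of the B cell-like cells coming from a library without the transcript. A knockout that keeps the counted 3-prime end of the transcript, a small share of cells without it and a table holding the WT library only all remain open, and the test says nothing about which sample a cell came from.

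Haemoglobin UMIs per cell in macrophage-like cells were 3.94 times those in T cell-like cells (3.88 to 4.0), with means of 108 and 27.5 although the macrophage-like cells were shallower (757.5 against 6897 UMIs). The interval covers counting error only and not the spread between cells. The ratio argues against free RNA spread over all droplets as the whole cause, but through the few cells with the most haemoglobin UMIs. The 5% of macrophage-like cells with the most haemoglobin UMIs, 18 cells, held 96.3% of them, and the median macrophage-like cell had 3 against 9 in T cell-like cells. A few doublets with red cells may therefore account for the excess in UMIs per cell. As a share of its own UMIs, the median macrophage-like cell had more haemoglobin (0.385% against 0.127%), with fewer haemoglobin UMIs and lower depth. A few doublets do not explain this higher share. Because the same UMIs take a larger share of a shallow cell, it shows no excess of haemoglobin UMIs in the median cell. The cause of the higher share stays open. Of the 14 cells in a subcluster led by the erythroid gene Alas2, 8 came from the macrophage-like class, and the subcluster's median doublet score was 0.073 against 0.039 in all kept cells. Uptake of red cells, which splenic macrophages carry out, was not tested and remains open.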
